A study of Mus musculus with 8 samples.

How the data were processed

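RNA of sorted cochlear hair cells of mice was measured in 8 libraries, 4 wild type and 4 Ndp knockout. Per the labels' protocols, each tube held 12 to 20 sensory epithelia, dissociated with TrypLE and sorted for Atoh1-GFP. RNA was extracted with the RNeasy Plus Micro Kit, and full-length cDNA was made with SMART-Seq v4, per the labels' protocols. Libraries came from Nextera XT, per the labels' protocols, a kit that does not mark the strand, so reads of overlapping antisense genes cannot be told apart.

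The authors deposited a single table of 25343 genes. Its signal columns hold the authors' normalized gene counts, which are counts divided by 1 size factor per library, as the values show. The submitters' processing notes name bcl2fastq 2.20, Salmon 0.14.2, DESeq2 1.26.0 and the build mm10, without their roles. The deposited table also gives the authors' own log2 fold changes, shrunken and unshrunken, and p-values of a DESeq2 comparison, per the file headers, and 265 genes have no p-value there. The smallest total of recovered reads of any gene in it was 10, and genes under that total were not analysed here. Coordinates are those of the deposited table. Of the gene names, 22 occur for more than 1 gene, and gene IDs are unique.

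Whole reads were recovered by dividing each column by its smallest step, and 100% of 202744 values lay within 1e-06 of a whole number. Whole numbers do not show whether these were counted reads or rounded estimates, since the role of Salmon is not given. They are called reads here. The wild-type replicates 1 to 4 held 37494307, 44149341, 48329827 and 35077950 reads, and the knockout replicates 1 to 4 held 37493185, 40624880, 44893293 and 35836310. A floor of 3 reads in a library was worth 2.34 to 3.49 normalized counts. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only. The mean chi-square of reads per gene was at least 32.0 for pairs of libraries within a genotype, where sampling noise alone gives about 1.

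Groups came from the genotype labels. Replicate numbers follow accession order and pair no libraries. Titles hold dates, and only 1 date occurs in both genotypes (wild-type replicate 2 and knockout replicate 2), so date could not be a block.

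The design, fixed before the data were examined, named edgeR for counts and limma on log2 values if the table held normalized values. The table held normalized values, so the main test was limma 3.58.1 in R 4.3.3 with an intensity trend and empirical Bayes moderation on log2(normalized count + 1), as a two-sided test, with Benjamini-Hochberg adjustment and a threshold of 0.05. For genes with low counts a fold change on this scale can be too small or too large. Adding 1 draws it toward 0, while a single library near 0 can enlarge it. The log2 difference was -6.42 by limma and -9.62 by edgeR for CR974586.1, and 3.20 and 1.04 for Lyz2. Genes with a normalized count of at least 10 in at least 4 libraries were tested, 18203 in all. That minimum was chosen after the table was seen and before any model was fitted. SDs are of normalized counts, and SEs are those of the moderated log2 difference.

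Gene lists fixed before the data were examined (29) were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 27 lists tested. The sex-linked list was a check, and the red blood cell list had fewer than 3 measured genes. Camera compares a list with all other genes, while fry asks whether its genes move, on balance, one way. At the preset correlation 8 lists passed, 6 higher and 2 lower, and 11 had an unadjusted p under 0.05. Camera with an estimated correlation called 0 lists, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.463. Fry called 0 lists, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.468.

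The rule for named genes took Ndp, up to 10 called genes per direction whose genotypes did not overlap in CPM and that were not unnamed models (0 qualified), 17 key genes of norrin signalling and hair cells, and up to 4 genes of each list with the smallest p, 124 genes in all. Other members of the lists, CR974586.1, Gm4810 and genes taken from the authors' deposited table were chosen after their values were seen.

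The tests were tried on simulated data over 18203 genes. Of 100 genes changed 2-fold limma called 18, and of 100 changed 4-fold 66, with 3 false calls. edgeR called 20 and 65, with 2 false calls. A 1.5-fold rise of the macrophage list in simulated data was not called by camera (adjusted p = 0.599). Rises of 2 and 4 times and a rise of the outer hair cell list were therefore added to the simulation. The 2-fold rise of the macrophage list was called (7.03e-05), as was a 1.5-fold rise of the outer hair cell list (3.14e-16). Of 50 simulated draws without any change, 1 gave a list call, with genes drawn independently, which leaves out the correlation between genes of real libraries.

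The alternatives fixed with the design were pseudocounts of 0.1 and 5, no filter, a minimum of 5 CPM in 4 libraries, DESeq2 1.42.0, edgeR 4.0.16 with DESeq2 size factors and voom with sample weights on recovered reads, 1 surrogate variable from sva 3.50.0, the month of the title date, each library left out, the pair with the shared title date left out, and other thresholds. edgeR with TMM, TMM rescaling, adjustment for transcript length and GC content, leaving out the 2 libraries with the highest cell cycle scores, and the lists without the pair of the shared date were chosen after seeing the data. Fits without a library kept the genes tested in all libraries. Length and GC content came from reference transcripts and were known for 99.9% of the genes tested. For a single gene or list that passed in no setting, a change of sign smaller than 1 SE counts as no change. The values without each library of genes called over a list alone were computed after those calls were seen. The values of 1 gene are not reported here, and it was left out of the search for libraries far from the others of their genotype.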

Results

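Hair cells, the sensory receptor cells of the inner ear, were sorted from the cochlea of young mice with an Atoh1-GFP reporter, and their RNA was sequenced as full-length cDNA. The mice were wild type or carried a knockout of Ndp, the gene of the secreted protein norrin, which binds the receptor encoded by Fzd4. Each genotype had 4 libraries, each from a pool of 12 to 20 sensory epithelia of postnatal days 4 to 6 on a mixed C57BL/6 and 129 background. Whole reads recovered from the deposited normalized counts numbered 35077950 to 48329827 per library. Hair cell transcripts were abundant: the calcium-binding gene Calb1 had 183686 ± 17716 normalized counts in wild type and 191687 ± 13595 in the knockout (SD, n = 4 each). Supporting cell transcripts were abundant too, and Tectb, which encodes a protein of the tectorial membrane, had 214099 ± 73356 and 179660 ± 27911 (SD, n = 4 each). Pearson's r of the log2 values over 18203 genes, which are not independent replicates, was 0.922 to 0.955 for the 12 pairs of libraries within a genotype and 0.916 to 0.950 for the 16 pairs between genotypes. The reads of every pair of libraries differed by more than sampling noise, so each library counted as 1 sample. The labels do not say how the pools relate to litters, and p-values measure only the spread between these libraries, which may be technical.

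The targeted gene was examined first, as a check of the labels. Ndp (ENSMUSG00000040138, chromosome X, 16885521 to 16911774, minus strand, mm10) had 146 ± 53.2 normalized counts in wild type and 36.2 ± 24.9 in the knockout (SD, n = 4 each). The wild-type libraries 1 to 4 held 174, 90.4, 114 and 206 normalized counts of Ndp and the knockout libraries 1 to 4 held 10.5, 22.6, 66.8 and 45.1, so every knockout library lay below every wild-type library. The log2 difference of Ndp was -2.20 ± 0.56 (SE), with an adjusted p of 0.895 in limma over all genes, so Ndp was not called. In the authors' deposited table the adjusted p of Ndp was 0.129. Which part of Ndp the knockout allele lacks is not given in the sources used here, and gene totals do not show where along the gene the remaining reads lie. Of 13 genes fixed as neighbours of Ndp on the X chromosome, 9 had a positive and 4 a negative log2 difference, and the list had a camera adjusted p of 0.527, with 0 genes at an unadjusted p under 0.05. Ddx3x, an RNA helicase gene, had 5876 ± 950.5 normalized counts in wild type and 5337 ± 449 in the knockout, and Usp9x, a deubiquitinase gene, had 4944 ± 1632 and 5544 ± 736 (SD, n = 4 each).

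The main comparison asked which genes differed between knockout and wild-type hair cells. CR974586.1, a protein-coding model on the unplaced scaffold JH584293.1 (203931 to 206144), fell in the knockout (adjusted p = 0.0313, limma) and was the 1 gene called among 18203. It lies outside the rule for naming genes and was chosen after its values were seen. No read of CR974586.1 was recovered in any knockout library, while the wild-type libraries held 48.8 to 182 normalized counts. Its wild-type mean of 95.9 was 127 times a floor of 0.757, which is 3 reads over the knockout group. Genes on unplaced scaffolds can share reads with close copies, so its level is uncertain. Limma called 0 genes higher in the knockout, and at an unadjusted p under 0.05 it listed 1014 genes, 564 higher and 450 lower. edgeR's quasi-likelihood test on the recovered reads called 0 of 18174 genes, with 827 at an unadjusted p under 0.05. DESeq2 called 34 of 25078 genes, 23 higher and 11 lower, with 1526 at an unadjusted p under 0.05, and its genes include some below limma's minimum count. With no difference a share of about 0.05 of the genes tested has an unadjusted p under 0.05. edgeR's count lay below that share, and those of limma and DESeq2 lay above it. Among the members of the gene lists fixed before the data were examined, DESeq2 called 1, Coch. The normalized counts of the genotypes did not overlap for 553 genes, 3.04% of those tested, and their CPM for 547, where chance gives 2.86%. The adjusted p of CR974586.1 was 0.288, 0.275, 0.261 and 0.152 without wild-type replicate 1, 2, 3 and 4, and 0.0871, 0.102 and 0.108 without knockout replicate 1, 3 and 4. Without knockout replicate 2 it was 0.0449, and the model Gm4810 was then called as well (0.0449).

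The authors' deposited table holds a DESeq2 comparison of the same libraries, with 34 genes at an adjusted p under 0.05, 23 higher and 11 lower in the knockout, and DESeq2 on the recovered reads called the same 34 genes. The genes named here were chosen after their values were seen. In the authors' deposited table Nr4a3, which encodes an orphan nuclear receptor induced by stimulation, had an unshrunken log2 fold change, knockout over wild type, of -2.08 (adjusted p = 1.07e-08), and Il1rapl1, an X-linked gene of a synaptic membrane protein, had 2.68 (adjusted p = 2.51e-08). Nr4a3 had 376 ± 77.03 normalized counts in wild type and 89.2 ± 23.7 in the knockout, and Il1rapl1 had 19.3 ± 6.51 and 123 ± 26.3 (SD, n = 4 each). Higher in the knockout in the authors' deposited table were also Inpp5d, the gene of an inositol phosphatase of blood cells (adjusted p = 2.39e-05), Vav1 (5.21e-05), Tlr4, a toll-like receptor gene (0.0488), and Cd52 (0.0488). Inpp5d had 1.54 ± 1.32 and 54.7 ± 27.1 normalized counts and Tlr4 had 10.6 ± 12.1 and 93.3 ± 27.4 (SD, n = 4 each). Macrophage markers had a mean log2 difference of 1.60 between the same libraries. Vav1 had 0 reads in every wild-type library and 35.6 ± 20.2 normalized counts in the knockout (SD, n = 4). Among genes with higher counts, Rrbp1, which encodes a ribosome-binding protein of the endoplasmic reticulum, had 3156 ± 263 and 1863 ± 264 normalized counts, and Nampt, which encodes an enzyme of NAD synthesis, had 1066 ± 63.8 and 1525 ± 43.2 (SD, n = 4 each). The adjusted p of Rrbp1 was 0.000406 and that of Nampt 0.000860 in the authors' deposited table. Cd52 was below the minimum count for limma, and none of the other genes named here passed there, with adjusted p of 0.280 for Nr4a3, 0.315 for Il1rapl1, 0.620 for Rrbp1 and 0.895 for Nampt.

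**Figure D1:**
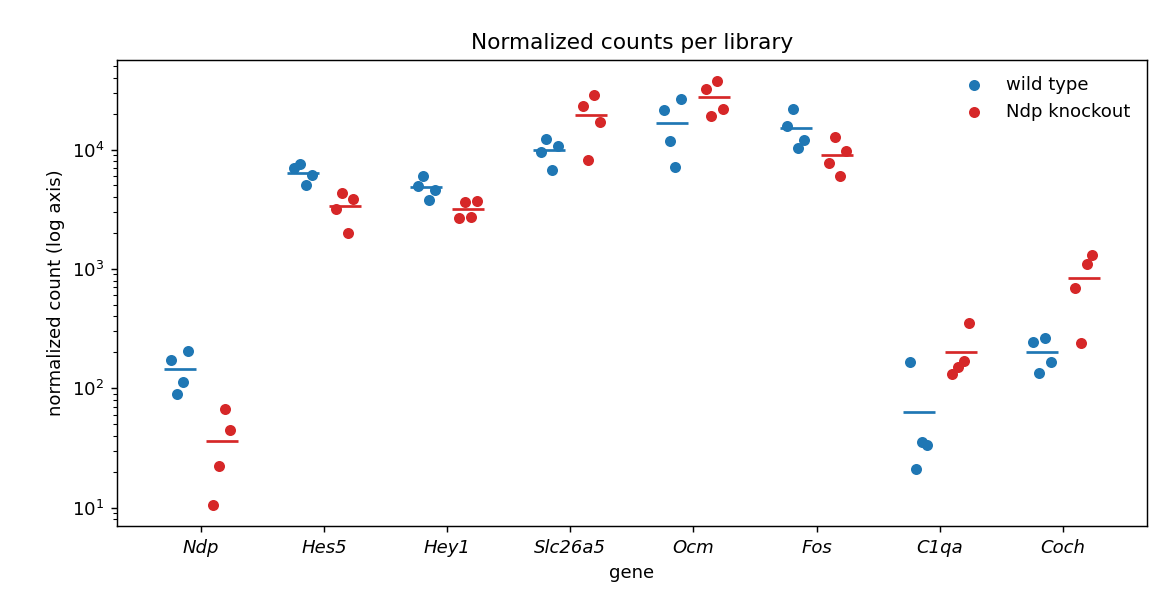
Normalized counts (log axis) of 8 genes in each of the 4 wild-type (blue) and 4 Ndp knockout (red) libraries, with points for libraries and short lines for group means. Every knockout library lay below every wild-type library for Ndp, Hes5 and Hey1, and the groups of Slc26a5, Ocm, Fos, C1qa and Coch overlapped.

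Genes of hair cell identity were compared next. Pou4f3, a transcription factor that hair cells need to survive, had 5961 ± 611 normalized counts in wild type and 5758 ± 325 in the knockout, and Atoh1, the factor that starts hair cell fate, had 3581 ± 1334 and 2821 ± 496 (SD, n = 4 each). Gfi1, a further hair cell transcription factor, had 7403 ± 998 and 8949.7 ± 813 normalized counts, and the hair cell myosin gene Myo7a had 15219.5 ± 7000.4 and 15672 ± 2595 (SD, n = 4 each). None of these genes passed in limma. Limma called 0 of 14 hair cell transcription factors, 0 of 22 general hair cell markers, 0 of 25 hair bundle genes and 0 of 12 mechanotransduction genes over all genes and 0 adjusted over the list alone, with 1, 2, 1 and 1 at an unadjusted p under 0.05, and edgeR called 0. The camera adjusted p was 0.947 for the transcription factors, 0.840 for the general markers, whose median (0.03) and mean (-0.06) differed in sign, 0.106 for the bundle genes and 0.798 for mechanotransduction. Tmc1, which encodes a subunit of the mechanotransduction channel, had 6702 ± 956 and 9391 ± 2209 normalized counts (SD, n = 4 each), a log2 difference of 0.47 ± 0.19 (SE). The 16 ribbon synapse genes had a camera adjusted p of 0.0970 and the 12 inner hair cell genes 0.106, with 0 members called by limma over all genes, 0 adjusted over the list alone, 0 and 0 at an unadjusted p under 0.05, and 0 called by edgeR. Otof, the calcium sensor gene of hair cell synapses, had 41592 ± 15987 and 52394 ± 6857 normalized counts (SD, n = 4 each). Bundle genes passed camera without wild-type replicate 3 (adjusted p = 0.000426) and inner hair cell genes without knockout replicate 4 (0.0468). Ribbon synapse genes passed without wild-type replicate 3 (0.0116), knockout replicate 2 (0.0314) or knockout replicate 4 (0.0498).

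The list of outer hair cell and maturation genes rose in the knockout. Of 19 members, 18 had a positive log2 difference, with a mean of 0.44 and a camera adjusted p of 9.54e-06 at the preset correlation. The adjusted p = 0.463 with an estimated correlation. No single member passed: limma called 0 over all genes and 0 adjusted over the list alone, 3 had an unadjusted p under 0.05, and edgeR called 0. Slc26a5, which encodes prestin, the motor protein of outer hair cells, had 9849 ± 2339.6 normalized counts in wild type and 19269 ± 8875 in the knockout (SD, n = 4 each), a log2 difference of 0.86 ± 0.34 (SE). Ocm, the gene of the calcium buffer oncomodulin, had 16711 ± 8852 and 27694 ± 8536 normalized counts (SD, n = 4 each), a log2 difference of 0.85 ± 0.38 (SE). Over 14 alternative settings the log2 difference of Ocm was 0.50 to 1.13. Aqp11, an aquaporin gene, had 10986 ± 3049 and 16017 ± 3854 normalized counts (SD, n = 4 each), and its genotypes overlapped. The potassium channel gene Kcnn2 had 2891 ± 387 and 3526 ± 198 (SD, n = 4 each), with no overlap of the genotypes. In the pair of libraries with the same title date Slc26a5 had 12302 normalized counts in wild type and 8147 in the knockout, opposite to the means. The mean log2 difference of the list was 0.25 in that pair and 0.51 in the other 6 libraries.

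Norrin acts through a receptor complex that activates Wnt signalling, so genes of the receptors and targets were compared. The receptor gene Fzd4 had 7008 ± 1825 normalized counts in wild type and 6905 ± 238 in the knockout (SD, n = 4 each). The log2 differences of the co-receptor genes Lrp5, Lrp6 and Tspan12 were -0.27 ± 0.31, -0.07 ± 0.22 and -0.11 ± 0.21 (SE), and those of Fzd4, Lrp6 and Tspan12 changed sign under some alternatives. Fzd9, another frizzled receptor gene, had 14442 ± 3611 and 9652 ± 2153 normalized counts (SD, n = 4 each), a log2 difference of -0.58 ± 0.22 (SE) with a limma adjusted p of 0.895. Ctnnb1, the gene of beta-catenin, had 23762 ± 3404 and 22049.6 ± 2233 (SD, n = 4 each). Of 24 receptor and pathway genes, limma called 0 over all genes and 0 adjusted over the list alone, 4 had an unadjusted p under 0.05, and edgeR called 0. The list had a camera adjusted p of 0.257, its mean (0.02) and median (-0.11) differed in sign, and it passed in the lower direction without wild-type replicate 4 (0.0153) or with 1 surrogate variable (0.0490). Axin2, Lef1 and Lgr5, targets of Wnt signalling, had log2 differences of 0.12 ± 0.54, 0.10 ± 0.43 and -0.08 ± 0.18 (SE), and each changed sign under some alternatives. Axin2 had 45.7 ± 19.0 and 54.8 ± 30.9 normalized counts and Lef1 152 ± 15.0 and 189 ± 112 (SD, n = 4 each). Of 19 Wnt targets, limma called 0 over all genes and 0 adjusted over the list alone, 2 had an unadjusted p under 0.05, edgeR called 0, and the camera adjusted p was 0.840.

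Supporting cells surround hair cells and exchange Notch signals with them. The Notch effector genes Hes5 and Hey1 were lower in every knockout library than in any wild-type library. Hes5 had 6400.4 ± 1093 normalized counts in wild type and 3342 ± 1019.8 in the knockout (SD, n = 4 each), a log2 difference of -0.98 ± 0.23 (SE), and Hey1 had 4826 ± 941 and 3177 ± 567 (SD, n = 4 each), a log2 difference of -0.60 ± 0.18 (SE). Hes1, whose genotypes overlapped, had 2334 ± 871 and 1346 ± 362 normalized counts, and Sox2, a factor of progenitors and supporting cells, had 4492 ± 833 and 3412 ± 602 (SD, n = 4 each). The gap junction gene Gjb2 had 30979.8 ± 6676 and 36213 ± 6525 (SD, n = 4 each). Of 30 supporting cell markers, limma called 0 over all genes and 1, Hes5, adjusted over the list alone (adjusted p = 0.0496), 4 had an unadjusted p under 0.05, and edgeR called 0. The limma adjusted p of Hes5 over the list alone was 0.177, 0.0864 and 0.108 without wild-type replicate 1, 2 and 4, and 0.145, 0.0733 and 0.0640 without knockout replicate 1, 3 and 4, and 0.0259 and 0.0267 without wild-type replicate 3 and knockout replicate 2. As a list the markers had a camera adjusted p of 0.106, with 19 negative and 11 positive log2 differences, and passed in the lower direction without wild-type replicate 3 (0.000426). In the pair with the same title date Hes5 had 7528 normalized counts in wild type and 4348 in the knockout, and Hey1 had 6041 and 3654.

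**Figure D2:**
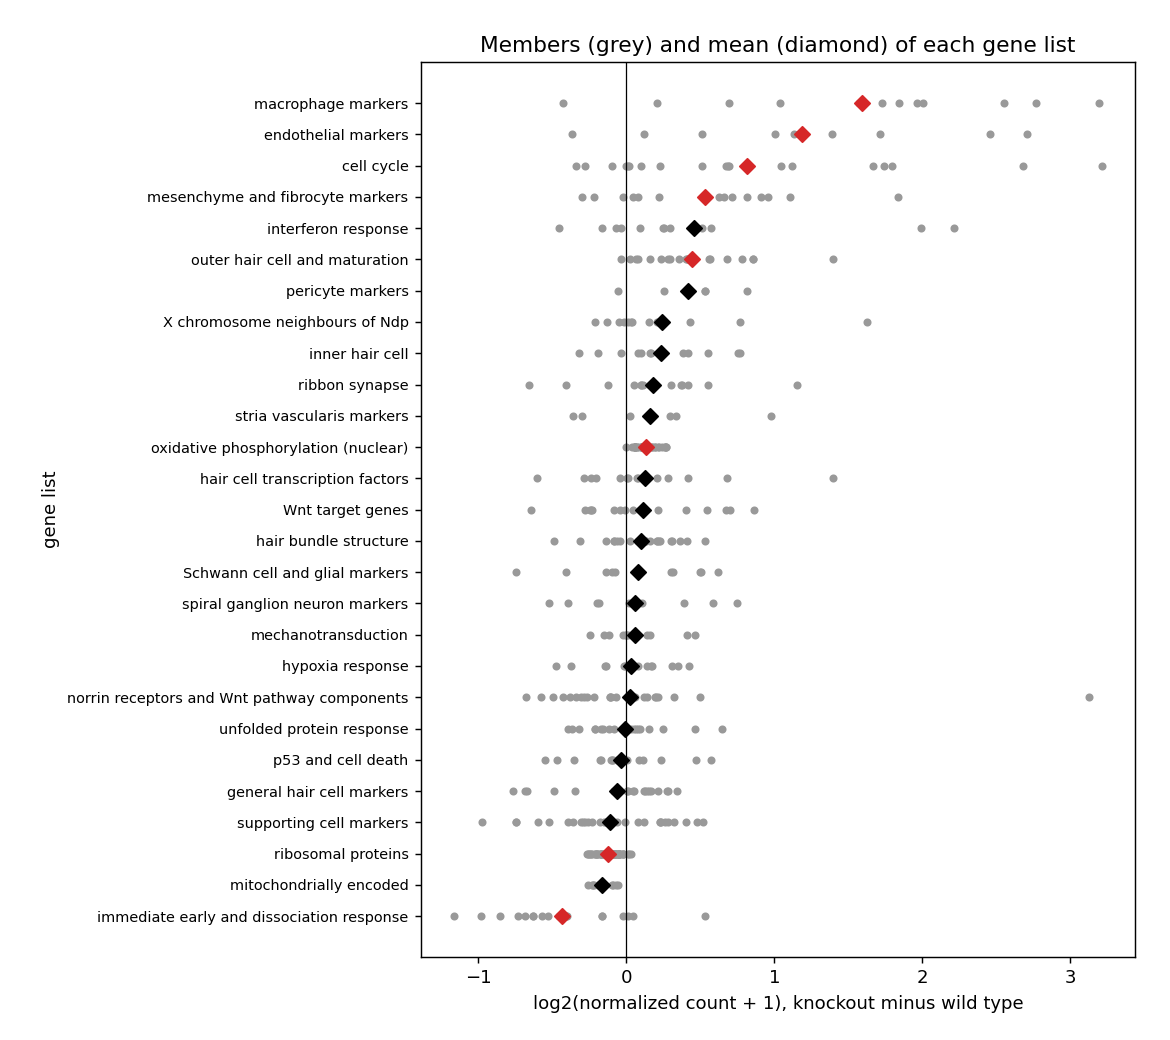
Differences of log2 values (knockout minus wild type, horizontal axis) for the members of 27 gene lists (grey points) and the mean of each list (diamond, red where the camera adjusted p at the preset correlation was under 0.05 and black elsewhere). The mean was 1.60 for the macrophage markers and -0.44 for the immediate early genes.

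Markers of other cell types that the sort could carry over were compared as well, and 3 of these lists rose in the knockout. Macrophage markers had a mean log2 difference of 1.60, with 11 of 12 positive and a camera adjusted p of 1.66e-06, and the adjusted p = 0.463 with an estimated correlation. C1qa, a complement gene of macrophages, had 63.8 ± 67.6 normalized counts in wild type and 201 ± 102 in the knockout, and the lysozyme gene Lyz2 had 302 ± 509 and 620.3 ± 278 (SD, n = 4 each). Wild-type replicate 1 held 165 normalized counts of C1qa and 1061 of Lyz2, while the other 3 wild-type libraries held 21.0 to 35.9 and 4.68 to 121. C1qb had 2043 ± 346 and 2353 ± 312 normalized counts (SD, n = 4 each). Endothelial markers had a mean of 1.19 over 9 genes with a camera adjusted p of 0.0146, and the adjusted p = 0.463 with an estimated correlation. Tek, which encodes an endothelial receptor, had 5.64 ± 6.51 and 31.5 ± 30.4 normalized counts (SD, n = 4 each). With such low counts the endothelial mean depended on the pseudocount. It was 1.62 with a pseudocount of 0.1 and 0.81 with 5, and the list passed with both. A minimum of 5 CPM in 4 libraries left too few endothelial genes for a test. For macrophage and endothelial markers limma called 0 genes over all genes and 0 adjusted over the list alone, with 5 and 1 at an unadjusted p under 0.05, and edgeR called 0. The endothelial call ended without wild-type replicate 2 (adjusted p = 0.133), knockout replicate 4 (0.110) or both libraries of the shared title date (0.0916). In the pair of that date and in the other 6 libraries the mean was 2.19 and 1.40 for macrophage and 1.06 and 1.23 for endothelial markers. The macrophage mean was 2.40 with 1 surrogate variable and 2.49 without wild-type replicate 1 and knockout replicate 1, the 2 libraries with the highest cell cycle scores, and the list passed in both settings.

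Mesenchyme and fibrocyte markers also rose as a list. Their mean log2 difference was 0.53, with 11 of 14 positive and a camera adjusted p of 0.0115, and the adjusted p = 0.479 with an estimated correlation. Coch, a gene of fibrocytes in the cochlea, had 203 ± 62.1 normalized counts in wild type and 836 ± 473 in the knockout (SD, n = 4 each), and the collagen gene Col1a2 had 2558 ± 761 and 4091 ± 1405 (SD, n = 4 each). Limma called 0 members over all genes and 1, Coch, adjusted over the list alone (adjusted p = 0.0421), 3 had an unadjusted p under 0.05, and edgeR called 0. Over the list alone the limma adjusted p of Coch was 0.0707, 0.142, 0.0599 and 0.125 without wild-type replicate 1, 2, 3 and 4, 0.101, 0.0764 and 0.150 without knockout replicate 1, 3 and 4, and 0.000491 without knockout replicate 2. The call of the list ended without wild-type replicate 4 (adjusted p = 0.172) or knockout replicate 4 (0.110), where the mean was 0.32. The mean of the list was -0.12 in the pair with the same title date and 0.75 in the other 6 libraries.

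Pericyte, glial, neuronal and strial markers did not pass. The camera adjusted p was 0.299 for 5 pericyte markers, 0.884 for 10 Schwann cell and glial markers, 0.947 for 10 markers of spiral ganglion neurons and 0.540 for 7 markers of the stria vascularis. In these lists limma called 0 genes over all genes and 0 adjusted over the list alone, with 0, 0, 2 and 0 at an unadjusted p under 0.05, and edgeR called 0. Pmp22, a myelin gene, had 543 ± 235 normalized counts in wild type and 1010.4 ± 868 in the knockout, and the neurofilament gene Nefm had 6619.6 ± 886 and 5055 ± 788 (SD, n = 4 each). The Schwann cell list had a median of 0.11 and a mean of 0.08, while camera's direction was down. Of the red blood cell genes only Alas2 passed the minimum count, at 20.9 ± 14.1 and 21.0 ± 26.9 normalized counts (SD, n = 4 each), and that list was not tested.

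Immediate early genes, which respond within minutes to stimulation or to tissue dissociation, fell as a list in the knockout. Of 18 members 15 had a negative log2 difference, with a mean of -0.44 and a camera adjusted p of 9.41e-07, and the adjusted p = 0.463 with an estimated correlation. Fos had 14998 ± 5136 normalized counts in wild type and 8997 ± 2882 in the knockout, and Egr1 had 14773 ± 7038 and 8751 ± 2304 (SD, n = 4 each). Jun, for which every knockout library lay below every wild-type library, had 9565 ± 3009 and 6047 ± 1137 normalized counts (SD, n = 4 each). Limma called 0 members over all genes and 0 adjusted over the list alone, 7 had an unadjusted p under 0.05, and edgeR called 0. The mean of the list was -0.58 in the pair with the same title date and -0.39 in the other 6 libraries. It was -0.26 without wild-type replicate 2 (camera adjusted p = 0.00215) and -0.27 without knockout replicate 3 (0.000133).

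Stress and interferon genes did not pass as lists. The camera adjusted p was 0.698 for p53 and cell death genes, 0.604 for the unfolded protein response, 0.798 for the hypoxia response and 0.106 for the interferon response, which passed without knockout replicate 1 (0.0480) and without wild-type replicate 1 and knockout replicate 1 together (0.0342). Casp9, a gene of the apoptotic caspase cascade, had 459.5 ± 106 normalized counts in wild type and 673 ± 55.5 in the knockout, and Atf4, a transcription factor of the integrated stress response, had 2589 ± 404 and 1973 ± 301 (SD, n = 4 each). Their limma adjusted p was 0.895 and 0.895, and the normalized counts of the genotypes overlapped for Atf4 and did not for Casp9. Limma called 0 members of these lists over all genes and 0 adjusted over the list alone, with 3, 1, 0 and 1 at an unadjusted p under 0.05, and edgeR called 0.

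Cell cycle, respiratory chain and ribosomal protein genes passed the list test with uneven or small differences. Cell cycle genes rose with a mean log2 difference of 0.82 over 20 genes (camera adjusted p = 0.0224), and the adjusted p = 0.815 with an estimated correlation. Ccnb1, a mitotic cyclin gene, had 1136 normalized counts in knockout replicate 1 and 55.0 to 193 in the other 3 knockout libraries. Without knockout replicate 1 the mean of the list was 0.23 and camera's direction turned (adjusted p = 0.704), and the call ended without wild-type replicate 2 (0.0561), replicate 3 (0.301) or replicate 4 (0.371), or without the 2 libraries with the highest cell cycle scores (0.0875). The mean was 0.44 without wild-type replicate 4 and 1.28 without wild-type replicate 1. Nuclear genes of oxidative phosphorylation rose with a mean of 0.13, 35 of 36 being positive (camera adjusted p = 0.0128), and the adjusted p = 0.815 with an estimated correlation. Cyc1, a subunit gene of complex III, had 14237 ± 1116 and 17169.5 ± 1163 normalized counts (SD, n = 4 each), with no overlap of the genotypes. The call of this list ended without wild-type replicate 2 (adjusted p = 0.841), wild-type replicate 3 (0.758), knockout replicate 3 (0.0543) or both libraries of the shared title date (0.767), and its mean was 0.00, 0.02 and 0.33 without wild-type replicate 2, 3 and 4. Ribosomal protein genes fell with a mean of -0.12, 45 of 48 being negative (camera adjusted p = 0.0146), and the adjusted p = 0.851 with an estimated correlation. Without wild-type replicate 4, which held 23037 normalized counts of Rps2 beside 9429 to 11656 in the other wild-type libraries, the mean was 0.14 and the list passed in the opposite direction (adjusted p = 0.00192). The ribosomal call also ended without wild-type replicate 1 (0.0839) or knockout replicate 3 (0.257), with 1 surrogate variable (0.340, mean -0.06) and without the 2 libraries with the highest cell cycle scores (0.183), and the mean was -0.06 without knockout replicate 3, -0.31 without wild-type replicate 2 and -0.22 without wild-type replicate 3. In the pair with the same title date and in the other 6 libraries the mean was -0.38 and 1.21 for cell cycle genes, 0.51 and 0.0081 for oxidative phosphorylation and 0.54 and -0.34 for ribosomal proteins. With 1 surrogate variable the mean of cell cycle genes was 1.27 and that of oxidative phosphorylation 0.22. For these 3 lists limma called 0 genes over all genes and 0 adjusted over the list alone, with 0, 1 and 0 at an unadjusted p under 0.05, and edgeR called 0. The 13 mitochondrially encoded genes had a camera adjusted p of 0.106. They passed in the lower direction with all libraries on the edgeR fit with DESeq2 size factors (0.0478), and without wild-type replicate 2 (0.000504), wild-type replicate 3 (0.00202) or both libraries of the shared title date (0.00191), and the adjusted p = 0.851 with an estimated correlation. Their mean was 0.54 in the pair of that date and -0.40 in the other 6 libraries. Their share of reads was 3.08% in wild-type replicate 4 and 1.04% to 2.04% in the other 7 libraries.

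**Figure D3:**
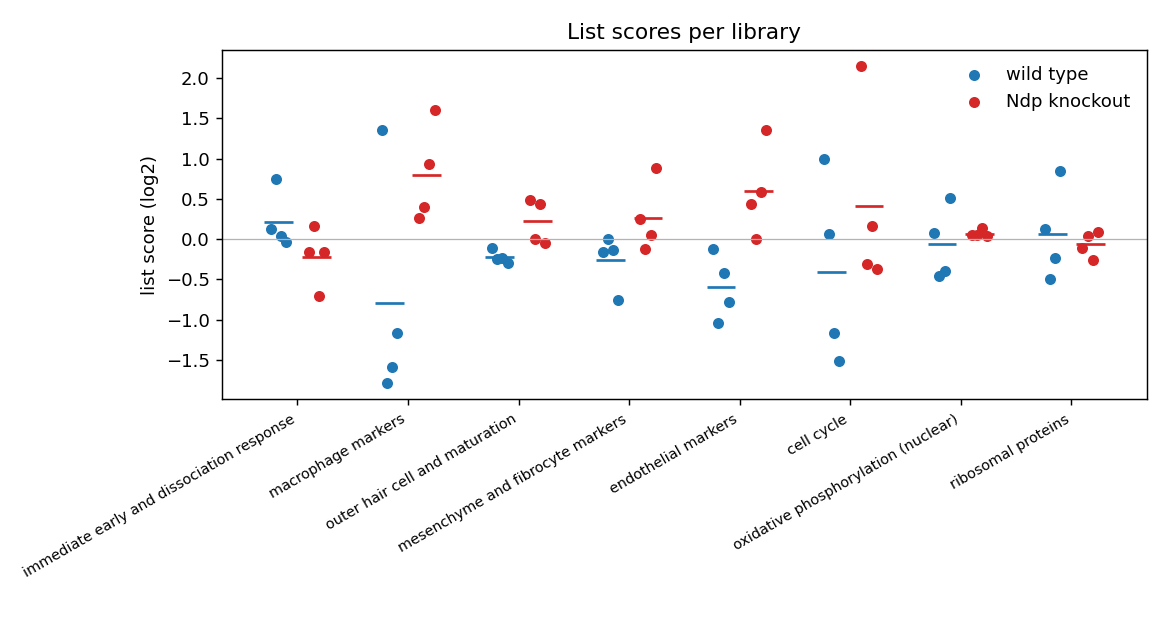
Score of each of the 8 gene lists past the camera threshold (mean log2 value per library, centred on the 8 libraries, vertical axis) in wild type (blue) and Ndp knockout (red), with points for libraries and short lines for group means. The macrophage score of wild-type replicate 1 was 1.36, and those of the knockout libraries were 0.27 to 1.60.

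Sex-linked genes served as a check of the make-up of the pools, since the sex of the animals is not given. Xist, transcribed from the inactive X chromosome of females, had 849, 768, 1064 and 1982 normalized counts in wild-type replicates 1 to 4. Knockout replicates 1 to 4 had 428, 0.981, 412 and 918, so knockout replicates 1 to 3 lay below every wild-type library. The log2 difference was -3.02 ± 1.56 (SE) for Xist, and 0.51 ± 0.35 and 0.68 ± 0.54 for the Y-linked genes Uty and Kdm5d. The genotypes overlapped for each, and none passed in limma. The sex make-up of the pools may thus differ between the genotypes, and its effect was not tested. The Y-linked gene Ddx3y had 2134 normalized counts in knockout replicate 2 and 491 to 1310.3 elsewhere. Wild-type replicate 2, which shares its title date with knockout replicate 2, had 768 normalized counts of Xist and 661 of Ddx3y.

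The last comparison asked whether genes that differed in 6 libraries moved the same way in the pair that shared a title date. Hes5, Hey1, Fos and Jun had log2 differences of -0.79, -0.72, -0.79 and -0.91 in that pair, with the sign of their means over all libraries. Slc26a5 (-0.59) and Tmc1 (-0.17) had the sign opposite to their means. Those means include the pair, and the genotypes of Hes5, Hey1 and Jun did not overlap, which fixed their sign in it. The signs of these named genes are therefore no held-out check. Limma on the 6 other libraries called 0 genes, so no share could be given at that threshold. At an unadjusted p under 0.01 there were 378 genes, of which 138 (36.5%) moved the same way in the held-out pair, beside 40.4% of all genes tested. In both sets fewer genes moved the same way than did not. That pair also had log2 differences of -8.60 for Xist, 2.03 for Uty and 2.87 for Kdm5d. Sex make-up and genotype cannot be told apart in it.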

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

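The tests of macrophage carry-over and of the share of hair cells were chosen only after the result was seen.

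A library stood far from the other 3 of its genotype in 19 of 302 groups of 4 values examined, where chance alone sets apart about 1 in 20 groups, or 15.1. Of the macrophage markers 3 were high in wild-type replicate 1: C1qa at 165 normalized counts beside 21.0 to 35.9 in the other wild-type libraries, Ctss at 329 beside 3.49 to 27.3, and Lyz2 at 1061 beside 4.68 to 121. C1qa also stood apart in knockout replicate 4, at 352 normalized counts beside 133 to 169.6. Macrophage markers rose as a list in the knockout (camera adjusted p = 1.66e-06, adjusted p = 0.463 with an estimated correlation), and they varied together within genotypes: their mean correlation of 0.540 lay at percentile 100 of 1000 gene sets of like expression. Macrophages carried over the Atoh1-GFP sort in numbers that vary between libraries would give this. Other lists varied together too, with an estimated correlation of 0.70 for cell cycle and 0.58 for oxidative phosphorylation genes. The correlation therefore cannot tell carry-over in the sort from differing macrophage numbers in the tissue. C1qb, at 2043 ± 346 and 2353 ± 312 normalized counts in the genotypes (SD, n = 4 each), was the most abundant of the 12 markers, 0 of which stand in another list, and which of them hair cells express was not analysed here. A lower share of hair cells raises markers of every other cell type alike. The supporting cell markers, which include Notch effector genes that fell, had a median log2 difference of -0.12 (SD over markers 0.38, highest 0.52) where 1.60 would be needed. The mean difference was 1.19 for endothelial, 0.53 for mesenchyme, 0.42 for pericyte, 0.16 for strial, 0.08 for glial and 0.06 for neuronal markers. These medians and means all lay below 1.60. Markers are not independent replicates and 1.60 is taken as fixed here, so this comparison cannot decide whether that share was the whole cause. Over libraries that share was not excluded: the gap between the macrophage and supporting cell scores had an exact two-sided permutation p of 0.114. That p was 0.0286, the smallest that 4 against 4 allow, only with the macrophage difference taken as fixed. The comparison over markers replaced that of the gap after its result was seen. More macrophages in the knockout cochlea, a biological explanation that the genotypes allow, was not tested.

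Knockout replicate 1 stood apart from the other knockout libraries in 3 cell cycle genes, with 989 normalized counts of Ccna2 beside 100.1 to 112, 1136 of Ccnb1 beside 55.0 to 193 and 417 of Cenpf beside 151 to 174. It also held 819 normalized counts of Meis1, a strial marker, beside 88.4 to 131. Knockout replicate 3 was low in Atoh1, at 2081 normalized counts beside 3029 to 3141, and high in Usp18, at 38.8 beside 17.7 to 19.0. Its oxidative phosphorylation score was 0.14 beside 0.03 to 0.05. In wild-type replicate 2 Atp2a3, a calcium pump gene, was at 24124 normalized counts beside 7709 to 9545 in the other wild-type libraries, and Tmie, of the mechanotransduction complex, was at 2159 beside 3032 to 3169. Fzd10 was at 22.8 normalized counts there, with 0 reads in the other wild-type libraries. Wild-type replicate 3 held 74.1 normalized counts of Axin2 beside 33.7 to 39.3 and 56.1 of Tie1 beside 1.06 to 3.65. In wild-type replicate 4 Rps2 was at 23037 normalized counts beside 9429 to 11656, and Atp1b2 at 4295 beside 7701 to 8236. Irf7 had 0 reads in wild-type replicate 1 beside 21.9 to 24.4 normalized counts.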

How the results depend on the processing

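The settings of edgeR with TMM, of TMM rescaling, of length and GC content, of the 2 libraries with the highest cell cycle scores and of the lists without the pair of the shared date were tests chosen only after the result was seen. Limma's count of called genes, 1 with all libraries, was 0 with a pseudocount of 0.1, 0 with the stricter filter, which did not test CR974586.1, 0 with 1 surrogate variable, 0 with the month as covariate, 0 without the pair of the shared title date, and 0 without the 2 libraries with the highest cell cycle scores. edgeR called 0 genes with TMM and 0 with DESeq2 size factors, with 827 at an unadjusted p under 0.05 with TMM, and DESeq2 called 34. With 1 library left out limma called 0 to 2 genes. The adjusted p of CR974586.1 was 0.255 with a pseudocount of 0.1, 0.133 with a surrogate variable, 0.0849 with the month and 0.301 without the pair, and 0.0115 to 0.491 over the limma settings that tested it, beside 1.87e-09 by DESeq2 and 0.352 by edgeR with TMM. The count of called lists, 8, was 0 with an estimated correlation and 0 by fry, with 2 and 2 lists at an unadjusted p under 0.05. It was 6 to 10 with 1 library left out. The mean log2 difference of cell cycle genes was 0.0424 with the stricter filter (adjusted p = 0.981), with camera's direction down, and 0.23 to 1.28 with 1 library left out. That of ribosomal protein genes was -0.31 to 0.14 with 1 library left out. The cause was not tested for these changes, apart from the fewer genes or libraries in the settings that leave them out. The calls of immediate early, macrophage and outer hair cell genes at the preset correlation held without each of the 8 libraries. Over single lists and settings 481 results kept their side of the threshold, and their direction apart from changes of sign under 1 SE. Beside these, 33 calls ended, 14 were gained, 3 turned and 8 moved without a call. Only the 8 lists called with all libraries had a call that could end, and the 481 include the results of lists without a call. Over named genes 1729 did not change, 6 moved and 1, Coch by DESeq2, gained a call (adjusted p = 0.0119). Of 124 named genes 17 changed sign in at least 1 of 14 settings. In the limma fit of the 6 libraries outside the shared title date 378 genes had an unadjusted p under 0.01. Of these only 138 (36.5%) moved the same way in the pair of that date, beside 40.4% of all genes tested. That pair also differed in sex-linked genes, so sex make-up and genotype cannot be told apart in it. No paired analysis was possible because only 1 title date occurs in both genotypes, and replicate numbers, which follow accession order, pair no libraries.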

Other observations

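The tests of hair cell share, of hair cell stages and of a strain segment, the set of early genes, and Hes6, Dll3, Ccer2 and Lancl3 as named genes, were chosen only after the result was seen.

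Hes6, of the hair cell transcription factor list, had 6148 ± 1617 normalized counts in wild type and 4070.1 ± 1320.0 in the knockout, the Notch ligand gene Dll3 had 2007 ± 796 and 1182 ± 421, and Ccer2 had 27273 ± 10677 and 16934 ± 6280.4 (SD, n = 4 each). Their log2 differences were -0.61 ± 0.26, -0.76 ± 0.33 and -0.69 ± 0.30 (SE), the genotypes overlapped for each, and none passed in limma (adjusted p = 0.895 for Hes6). Over 14 alternative settings these differences were -0.81 to -0.44, -0.98 to -0.49 and -0.88 to -0.45. In the pair with the same title date the 3 genes were higher in the knockout, with log2 differences of 0.59, 0.41 and 0.48.

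Outer hair cell and maturation genes rose as a list in the knockout (camera adjusted p = 9.54e-06, adjusted p = 0.463 with an estimated correlation), and 5 of the 19 stand in another list as well. Adjustment for transcript length and GC content left 97.4% of their mean log2 difference, which went from 0.44 to 0.43 (camera adjusted p = 1.21e-05), so the data argue against length and GC content as the whole cause. For a larger share of hair cells in the sort, the general hair cell markers had a median log2 difference of 0.029 (SD over markers 0.33) where 0.44 would be needed. Over libraries the gap between the scores had an exact two-sided permutation p of 0.114, and of 0.0286 only with the outer difference taken as fixed. The comparison over markers replaced that of the gap after its result was seen. The general markers include Dll3, Ccer2 and Gng8, which also serve as early genes below. A mix of stages could lower that list, so a larger share of hair cells was not excluded. A different mix of hair cell stages may also contribute: within genotypes Pearson's r of the outer score and a score of 5 early genes (Atoh1, Hes6, Dll3, Ccer2 and Gng8) was -0.52 over 8 libraries (permutation p = 0.210), and Spearman's rho was -0.500 (permutation p = 0.212). Without the 2 libraries farthest from the median r was -0.52, and this was the 1 relation computed, so with 8 libraries a mix of stages cannot be told apart from an effect of the genotype, and a larger share of outer among all hair cells was not tested.

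Genes with 0 reads in 1 genotype and at least 5 reads in every library of the other numbered 6: CR974586.1 and Col6a4 in wild type, and Adcyap1r1, Vav1, Sla and 2810047C21Rik1 in the knockout. A strain segment carried with the Ndp allele predicts that they lie near Ndp, and 0% of the 5 on placed chromosomes lie on X within 20 Mb of it, which argues against that segment for those genes. It stays open for the 1 gene on an unplaced scaffold, CR974586.1, whose distance from Ndp is unknown, and for Lancl3 (X, 9199902 to 9268085), which lies within that window, had 0 reads in wild type and 24.6 ± 17.4 normalized counts in the knockout (SD, n = 4), and was not among the 6 because knockout replicate 2 held 0.981. Strain differences elsewhere in the genome stay open on this mixed background.

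The 8 libraries can be split into 4 and 4 in 35 ways, the real one included. As many called genes as in the real split (1) came from 7 splits, the highest other giving 1, and as many called lists (8) from 12, the highest other giving 12. As many genes at 0 reads in 1 group (6) came from 14 splits, the highest other giving 13, and as many DESeq2 calls (34) from 12, the highest other giving 170. Chance could not be excluded for any of these 4 counts. The split with 170 DESeq2 calls set wild-type replicates 1, 3 and 4 and knockout replicate 2 against the rest, which is the real split with the pair of the shared title date exchanged. A count several times the real one points to a structure of the samples, but this was the highest of the splits, and neither a count for libraries without structure nor a cause was tested. Ndp followed the labels in that pair, at 90.4 normalized counts in wild type and 22.6 in the knockout.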
